A study of Mus musculus with 10 samples.

How the data were processed

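Liver RNA of male mice was measured on Affymetrix GeneChip MG_U74Av2 arrays, which probe each transcript with sets of short oligonucleotides. Per the labels, 5 groups were studied. SCAP is the escort protein that SREBPs, the transcription factors of lipid synthesis, need for their activation, and the Scap knockout mice lacked it in liver. They and their wild type controls were 10 to 12 weeks old, ate chow, received 4 injections of polyinosinic-polycytidylic acid to switch on the Cre recombinase, and were killed 14 days after the last one. TgSREBP-1a and TgSREBP-2 mice carried active nuclear forms of human SREBP-1a or SREBP-2. They and their wild type littermates were 12 to 16 weeks old and spent 2 weeks on a diet rich in protein and poor in carbohydrate, called the high-protein diet here.

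Per the labels' protocols, RNA of 5 mice per group was combined in equal parts to 1 pool of 20 µg, and each pool was hybridised to 2 arrays. The 10 arrays are therefore 2 hybridisations of each of 5 pools. The p-values below measure the spread between hybridisations and compare pools, not genotypes. They carry no error between mice. The number of arrays limits the precision.

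The authors deposited 1 table of log2 values for 12488 probe sets. Per the submitters' processing notes the values were made with RMA, version not given in the sources used here, while the series' design text names Microarray Suite 5.0, which gives linear signals. The deposited values ran from 2.68 to 14.03 with medians of 6.36 to 6.4 per array and near-equal quartiles, so they were taken as log2 signals normalized between arrays. Detection calls were not used here. Duplicates correlated at 0.9921 to 0.9978 over genes, and no pair held identical values. Their spread was unequal. Genes at least 1.5-fold apart between duplicates numbered 151 in TgSREBP-1a, 101 in wild type on the high-protein diet and 55 in TgSREBP-2. In Scap knockout there were 6, and in chow-fed wild type 0.

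Probe sets were named through the platform annotation, updated by gene ID through RefSeq, where 10817 matched. Of the 12488 probe sets, 66 were controls, 10833 had 1 gene symbol, 396 had several and 1193 had none. Controls and probe sets with several or no symbols were left out. Each of 8251 genes was represented by its probe set with the highest mean over the 10 arrays. For 2073 genes there was a choice, and among called genes another probe set was called the opposite way for Srxn1 and Ly6d in TgSREBP-1a, for Srxn1 between the transgenic pools and for Tubb2a between the wild type pools. Srebf2 and Scap have no probe set of their own name in the annotation used and were not analysed here.

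The 10 arrays were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 coefficient per group, 5 residual degrees of freedom and no block. The contrasts numbered 5, each over 8251 genes with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 with at least a 1.5-fold difference. Errors given as ± after a log2 difference are the moderated standard errors of that fit, with n = 2 arrays per group. The fit shares 1 variance per gene over all groups, although duplicates differed more on the high-protein diet. Errors and p-values may therefore be too small for the transgenic comparisons and too large for Scap knockout. On data simulated from the real means, with changes of 1.5, 2 and 4-fold planted in 200 genes, the test called 53.7%, 100% and 100% of them for TgSREBP-1a, 50.7%, 97% and 100% for TgSREBP-2, and 47.8%, 98.5% and 100% for Scap knockout. It called 1, 2 and 2 unchanged genes. The simulation held only independent spread between hybridisations, equal in every group, and no difference between pools beyond the planted ones. It therefore sets no bound on false calls in the real pools.

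Duplicates share replicate numbers across groups, and the labels do not say what a number marks. In the data, deviations from the group means of same-numbered arrays correlated at 0.46, 0.61 and 0.60 among the 3 pools of the transgenic set, so the number was taken to pair arrays there. They correlated at 0.30 in the Scap set, which has 1 such pair of pools, and at -0.12 to -0.48 between the sets. A fit with the number as a block within each set was therefore added after the data were seen.

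Before the data were examined, the design, 27 gene lists (18 pathways and 9 sets of cell type markers), the alternatives and the rule for named genes were fixed. The rule takes the 10 largest increases and decreases per comparison with wild type among called genes whose 4 array pairs all have 1 sign, 6 each between the transgenic pools and 4 each between the wild type pools. It adds up to 4 members with the largest absolute difference per list, and up to 30 genes of the 3-way overlap. Genes named outside it were chosen after their values were seen, and are the members counted in a list and the genes of the closing section. For each list, members called were counted over all genes and adjusted over the list alone. The list's median was placed among 10000 random lists of equal size matched on mean signal in 20 bins, as a description of these pools. Set tests used camera of limma with a preset correlation of 0.01 and with an estimated correlation. Lists of skeletal muscle and squamous epithelium genes were added after the data were seen, and a list of further acinar genes before their own values were seen.

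Alternatives were quantile normalization, median centring, 32 added on the linear scale, the dimmest 40% of genes left out, an intensity trend or robust prior, only the arrays compared, thresholds of 2-fold, 3-fold, adjusted p alone or fold alone, a test against 1.5-fold (treat), the mean of a gene's probe sets, plain _at probe sets, the replicate number as a block, and each array left out. Figures were drawn with matplotlib 3.10.9.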

Results

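Liver transcripts were measured in 5 RNA pools, each of 5 male mice and each hybridised to 2 arrays. The title of the study gives its purpose as finding direct SREBP targets by combining transgenic and knockout mice. Against the wild type pool of the same diet, 608 of 8251 genes were called in TgSREBP-1a, 212 in TgSREBP-2 and 137 in Scap knockout. All tests compare pools with the limma fit described above, and n = 2 arrays per group throughout.

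Srebf1, the mouse gene of SREBP-1, was measured first because Srebf2, Scap and the human transgenes were not analysed here. Its log2 signal was 8.59 and 8.60 on the Scap knockout arrays against 10.07 and 10.14 in chow-fed wild type. It was 10.57 and 10.52 in TgSREBP-1a, 10.01 and 10.04 in TgSREBP-2, and 8.68 and 8.70 in wild type mice on the high-protein diet. Whether the mouse probe set also detects the human transgene is not known here, so this gene does not check the labels.

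In TgSREBP-1a livers the enzymes of fatty acid and cholesterol synthesis rose together. Scd2, a stearoyl-CoA desaturase, rose most, by 4.87 ± 0.09 log2 or 29.3-fold (adjusted p = 3.64e-10). The fatty acid elongase Elovl6 rose 14.1-fold (3.82 ± 0.12), fatty acid synthase Fasn 13.9-fold (3.80 ± 0.11), malic enzyme Me1 11.8-fold (3.57 ± 0.13) and Thrsp, a lipogenic regulator, 9.15-fold (3.19 ± 0.09). Of 13 measured genes of fatty acid and triglyceride synthesis, 12 rose and none fell, and the same 12 were called when adjusted over the list alone. The list's median was 2.47 (adjusted p = 0.0776 with an estimated correlation). Of 16 measured genes of cholesterol synthesis, 15 rose, also 15 adjusted over the list alone, with a median of 2.11 (adjusted p = 0.0505 with an estimated correlation). Among them Hmgcs1, which makes HMG-CoA, rose 8.94-fold (3.16 ± 0.21), Fdps 8.66-fold (3.11 ± 0.08) and Idi1 6.30-fold (2.66 ± 0.09).

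Of 6 genes of NADPH production, 5 rose, 5 adjusted over the list alone, including Pgd (2.09 ± 0.08) and Tkt (1.35 ± 0.10), with an adjusted p = 0.0776 with an estimated correlation. In the SREBP pathway and sterol uptake list, 3 of 6 rose, 3 adjusted over the list alone: Lpl at 2.19 ± 0.17, Srebf1 at 1.86 ± 0.07 and Npc2 at 1.74 ± 0.11 (adjusted p = 0.121 with an estimated correlation). Of 15 genes of sterol efflux and lipoproteins, 3 rose and 1 fell, the same numbers adjusted over the list alone. Pltp, the phospholipid transfer protein, rose by 2.94 ± 0.13 and Apoa4 by 2.61 ± 0.08, while Apob fell by 0.64 ± 0.13, under 1.5-fold without replicate 1 of wild type (-0.52) or replicate 2 of TgSREBP-1a (-0.54). Cidea, a lipid droplet protein, rose by 2.03 ± 0.12 and was the only 1 of its 6-gene list called. Other large increases were Ly6d (3.39 ± 0.10, but -0.68 and called lower on its dimmer probe set), the histocompatibility gene H2-Q1 (3.25 ± 0.12) and the mitochondrial acetate-activating enzyme Acss1 (3.08 ± 0.16).

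Some genes of hepatic functions other than lipid synthesis were lower in the TgSREBP-1a pool. Cyp7b1, an oxysterol hydroxylase, fell by 4.36 ± 0.11, or 20.6-fold, and the bile acid genes Baat and Cyp8b1 fell by 0.98 ± 0.10 and 0.86 ± 0.09. In that 12-gene list 3 fell and 1 rose, Abcc3, the same over the list alone (adjusted p = 0.229 with an estimated correlation). Of 5 male-biased liver genes, 4 fell, 4 adjusted over the list alone, among them Hsd3b5 at -2.69 ± 0.15 and Mup3 at -2.57 ± 0.08, with an adjusted p = 0.0399 with an estimated correlation, or 0.107 with the replicate number as a block as well. Of 5 female-biased genes, 2 rose, 2 adjusted over the list alone, Cyp17a1 and Cyp2b9 (1.88 ± 0.09 and 1.71 ± 0.10). The gluconeogenic genes Pck1, G6pc and Pcx fell by 1.66 ± 0.12, 1.28 ± 0.08 and 0.82 ± 0.07, and Pgam1 rose (under 1.5-fold without replicate 2 of wild type, 0.55), of 11 genes in the glycolysis and gluconeogenesis list. Of 16 amino acid and urea cycle genes, 4 fell, led by Otc (-1.52 ± 0.14), and 2 rose. Of 21 acute phase genes, 12 fell and 2 rose, also adjusted over the list alone. Serpina3n fell by 1.89 ± 0.08 and Saa4 by 2.01 ± 0.14, while Orm2 rose by 2.08 ± 0.08 (adjusted p = 0.26 with an estimated correlation). Of 15 genes of the unfolded protein response, 4 fell, including Xbp1 at -1.03 ± 0.24 and the chaperone Hspa5 at -0.95 ± 0.21 (adjusted p = 0.0776 with an estimated correlation). The calls of Xbp1 and Hspa5 were lost in limma without replicate 1 of wild type (adjusted p = 0.0953 and 0.0731), and that of Xbp1 also without replicate 2 of TgSREBP-1a (adjusted p = 0.0662). Ces3a (-3.52 ± 0.12), the complement gene C9 (-3.41 ± 0.09), Slc22a30 (-3.12 ± 0.21) and G0s2 (-2.99 ± 0.12), a lipase inhibitor, were among the largest decreases.

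Among PPAR alpha targets, 5 of 18 rose and 1 fell, the same over the list alone. Ehhadh rose by 2.49 ± 0.17 and Cyp4a14 by 2.18 ± 0.19, while Ppara itself fell by 1.24 ± 0.13 (adjusted p = 0.534 with an estimated correlation). Of 21 xenobiotic genes, 6 rose and 3 fell, with Gstm3 at 2.14 ± 0.10 and Cyp1a2 at -1.69 ± 0.08. Of 21 cell cycle genes only Ccnd1 was called (1.79 ± 0.12), and of 12 immediate early genes only Myc (0.66 ± 0.12). Myc fell short of 1.5-fold without replicate 2 of wild type (0.58) or replicate 1 of TgSREBP-1a (0.53), and its list had an adjusted p = 0.315 with an estimated correlation. Limma called 0 of 16 interferon-stimulated genes, while 5 had an unadjusted p under 0.05. Usp18 was at 0.47 ± 0.09 (adjusted p = 0.00492), short of 1.5-fold.

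Markers of other cell types also differed. Of 11 macrophage markers 5 rose, 5 adjusted over the list alone, led by Cd5l (1.53 ± 0.16) and C1qb (1.09 ± 0.09), with an adjusted p = 0.0776 with an estimated correlation. Of 8 endothelial markers Lyve1 and Cdh5 rose (adjusted p = 0.142 with an estimated correlation), Cdh5 only with replicate 1 of TgSREBP-1a included (0.58 without it). Of 10 lymphocyte markers Ighm rose (1.42 ± 0.08), but its plain _at probe set stood at -0.14. Of 5 adipocyte markers Car3 fell (-2.57 ± 0.12), and of 4 red cell markers Hba-a1 rose and Alas2 fell, Alas2 by under 1.5-fold without replicate 2 of wild type (-0.58) or replicate 1 of TgSREBP-1a (-0.52). Limma called 0 of 8 neutrophil, 10 stellate cell and 4 cholangiocyte markers, where 1, 7 and 1 had an unadjusted p under 0.05. All 7 measured exocrine pancreas markers fell, 7 also adjusted over the list alone. Prss2, a trypsinogen, fell by 5.56 ± 0.07, Ctrb1 by 4.26 ± 0.08 and Cela1 by 3.17 ± 0.07, with an adjusted p = 0.0362 with an estimated correlation, or 0.107 with the block as well. In total 394 genes were higher and 214 lower, of which 153 and 87 reached 2-fold. At an adjusted p under 0.05 alone, 1366 passed.

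In TgSREBP-2 livers every measured cholesterol synthesis gene rose, 16 of 16, also adjusted over the list alone. The median of 2.84 stood above all 10000 random lists and held with an estimated correlation (adjusted p = 0.0234). Idi1, which isomerises isopentenyl diphosphate, rose 19.9-fold (4.31 ± 0.09, adjusted p = 1.73e-09). The sterol methyl oxidase Msmo1 rose 14.9-fold (3.90 ± 0.19), Hmgcs1 14.3-fold (3.84 ± 0.21) and Cyp51 10.3-fold (3.37 ± 0.17). Fdft1, Dhcr7, Nsdhl, Fdps and Sqle rose by 3.18, 3.03, 2.96, 2.92 and 2.77 log2. Of 13 fatty acid and triglyceride genes 8 rose, 8 adjusted over the list alone, led by Scd2 (3.98 ± 0.09) and Fasn (2.75 ± 0.11), with an adjusted p = 0.0768 with an estimated correlation. Of 6 NADPH genes 5 rose, 5 adjusted over the list alone, led by Me1 and followed by Idh1 (0.84 ± 0.17), with an adjusted p = 0.0819 with an estimated correlation. Idh1 lost its call in limma without replicate 2 of wild type (adjusted p = 0.114) or replicate 1 of TgSREBP-2 (adjusted p = 0.172). Of the SREBP pathway list Srebf1 and Npc2 rose, 2 of 6, with Srebf1 at 1.34 ± 0.07. Of the lipoprotein list Pltp and Apoa4 rose, 2 of 15, with Apoa4 at 1.81 ± 0.08.

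Outside lipid synthesis, fewer genes differed in TgSREBP-2. Of 16 interferon-stimulated genes 7 rose, 7 adjusted over the list alone, including Psmb8 (1.07 ± 0.13) and Ifi27 (0.92 ± 0.09), with an adjusted p = 0.0695 with an estimated correlation. Of 21 acute phase genes 5 rose, led by Orm2 (1.93 ± 0.08) and Saa3 (1.30 ± 0.09), and Serpina3n and Apcs fell (adjusted p = 0.478 with an estimated correlation). The bile acid transporters Abcc3 and Abcc2 rose by 0.93 ± 0.09 and 0.81 ± 0.11. Of the PPAR alpha list Ehhadh rose, and Cyp4a10 and Acot1 fell. The call of Cyp4a10 was lost in limma without replicate 1 or 2 of wild type (adjusted p = 0.124 and 0.052) or replicate 2 of TgSREBP-2 (adjusted p = 0.112). Of 5 male-biased genes Hsd3b5 was called, at -1.74 ± 0.15 (adjusted p = 0.0695 with an estimated correlation). Of 12 immediate early genes Egr1 fell (adjusted p = 0.134 with an estimated correlation), by under 1.5-fold without replicate 1 of wild type (-0.50) or replicate 2 of TgSREBP-2 (-0.56). Of 21 xenobiotic genes Cyp3a11 and Aldh1a1 rose and Cyp1a2 fell, and Cyp3a11 lost its call in limma without replicate 2 of wild type (adjusted p = 0.0605) or replicate 1 of TgSREBP-2 (adjusted p = 0.0597). G0s2 fell most of all genes (-2.16 ± 0.12), followed after Hsd3b5 by Gstp1 (-1.52 ± 0.08), Serpina12 (-1.46 ± 0.08), Krt4 (-1.30 ± 0.12) and the iron hormone Hamp (-1.10 ± 0.08). The glucose transporter Slc2a2 fell by 1.04 ± 0.17. Macrophage markers Cd5l, C1qb and Lyz2 rose, 3 of 11 and 3 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Lyz2 lost its call in limma without replicate 2 of wild type (adjusted p = 0.0996) or replicate 1 of TgSREBP-2 (adjusted p = 0.167), and C1qb fell short of 1.5-fold without the latter (0.57). The exocrine pancreas markers Reg1 and Prss2 rose, 2 of 7, or 3 adjusted over the list alone and 3 with the block, which adds Pnliprp1 at 0.65 (adjusted p = 0.0695 with an estimated correlation), and of the red cell list Hba-a1 rose. Limma called 0 of 108 members in the remaining 11 lists, where 22 had an unadjusted p under 0.05. Among these, the medians of stellate cell (-0.16) and cholangiocyte markers (-0.23) stood below the middle of the random lists, with adjusted p = 0.134 and 0.271 with an estimated correlation. In total 180 genes were higher and 32 lower, 63 and 9 of them by 2-fold. Without replicate 1 of TgSREBP-2 only 110 were higher, and 21 were lower without its replicate 2 or with 32 added.

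**Figure D1:**
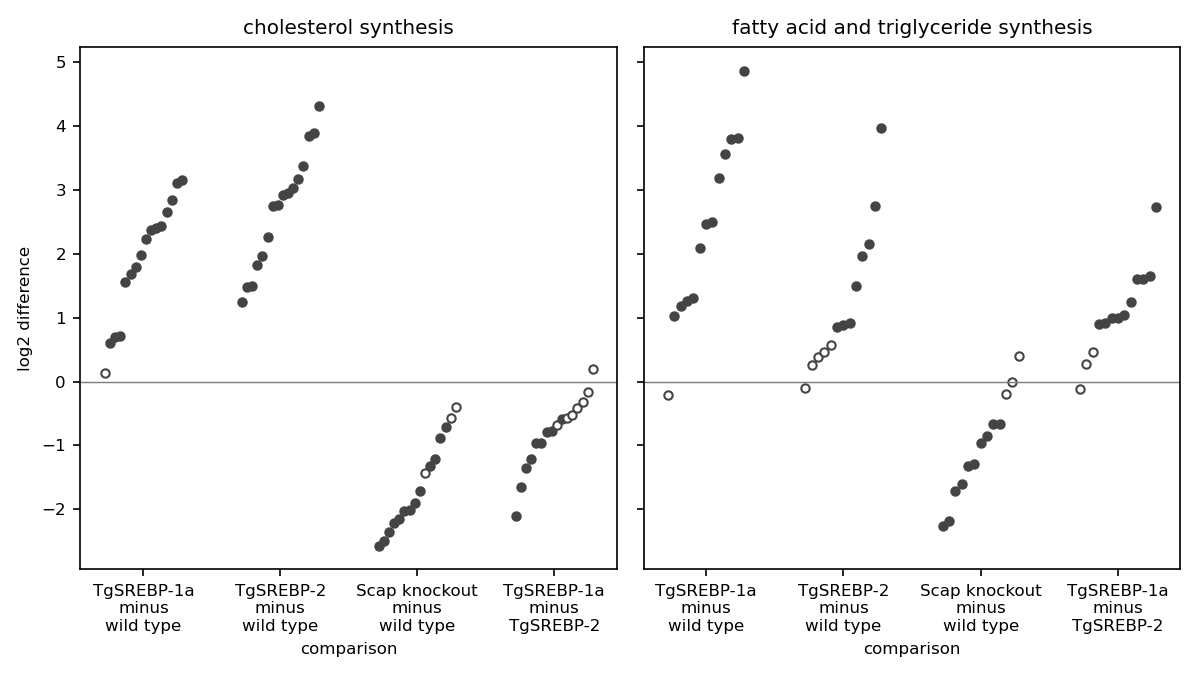
Log2 differences (y axis) of the measured genes of cholesterol synthesis (left, 16 genes) and of fatty acid and triglyceride synthesis (right, 13 genes) in 4 comparisons (x axis), each point a gene, ordered by value within a comparison; filled points were called and open points were not. Called cholesterol genes number 15, 16, 13 and 9, and called fatty acid genes 12, 8, 10 and 10, from left to right.

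The 2 transgenic pools were compared directly to ask which genes differed between the SREBP isoforms. Fatty acid genes were higher in TgSREBP-1a, 10 of 13 and 10 adjusted over the list alone. Thrsp was higher by 2.73 ± 0.09, Elovl6 by 1.66 ± 0.12 and Gpam, which starts glycerolipid synthesis, by 1.60 ± 0.09. Cholesterol genes were lower in TgSREBP-1a, 9 of 16, or 10 adjusted over the list alone. Msmo1 was lower by 2.10 ± 0.19 (log2 difference -2.10), Idi1 stood at -1.66 ± 0.09 and Mvk at -1.35 ± 0.10. Both lists had an adjusted p = 0.0808 with an estimated correlation. Lpl (2.02 ± 0.17), Ccnd1 (2.18 ± 0.12), Cyp17a1 (2.14 ± 0.09), H2-Q1 (3.31 ± 0.12), Ly6d (3.22 ± 0.10, but -0.19 on its dimmer probe set), Acss1 (2.97 ± 0.16), Cyp2c39 (2.67 ± 0.09) and Sprr1a (2.59 ± 0.09) were higher in TgSREBP-1a. Cyp7b1 (-3.95 ± 0.11), Saa2 (-2.56 ± 0.12) and Mup3 (-2.28 ± 0.08) were lower, as were 6 of 16 interferon-stimulated, 8 of 21 acute phase and all 7 pancreas genes. Of the 27 lists only the pancreas markers held with an estimated correlation (adjusted p = 0.016), but not with the block as well (adjusted p = 0.0812); interferon-stimulated and acute phase genes both had an adjusted p = 0.0808 with an estimated correlation. In total 428 genes were called, 185 higher and 243 lower in TgSREBP-1a. Which direction held more genes turned without replicate 2 of TgSREBP-1a (254 higher and 206 lower) and without replicate 1 of TgSREBP-2 (217 and 194). The nuclear SREBP protein of the 2 lines was not analysed here, so whether transgene levels matched is not known.

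Loss of Scap had the opposite direction for lipid synthesis. Of 16 cholesterol genes 13 fell, or 14 adjusted over the list alone, and none rose. The median was -1.81, which held with an estimated correlation (adjusted p = 0.00743). Idi1 fell by 2.57 ± 0.09, or 5.92-fold (adjusted p = 7.82e-08), Msmo1 by 2.35 ± 0.19 and Nsdhl by 2.22 ± 0.11, and Fdps was 5.65-fold lower. Of 13 fatty acid genes 10 fell, 10 adjusted over the list alone, led by the desaturase Scd1 (-2.26 ± 0.09) and Thrsp (-2.18 ± 0.09), with an adjusted p = 0.0589 with an estimated correlation. Srebf1 fell by 1.51 ± 0.07. Srebf1 was 1 of 6 called in its list and Me1 1 of 6 NADPH genes (-1.30 ± 0.13), and both lists had an adjusted p = 0.124 with an estimated correlation.

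Other lists held few calls in the Scap knockout pool. Cell cycle genes Cdc20, Ccnd1 and Cdk1 rose (1.26 ± 0.10, 1.09 ± 0.12 and 1.02 ± 0.09), 3 of 21 and 3 adjusted over the list alone, and the list had a median of 0.25, with an adjusted p = 0.00743 with an estimated correlation, or 0.0595 with the block as well. Of the interferon list Psmb9, Tap1 and Psmb8 fell, 3 of 16 (adjusted p = 0.0724 with an estimated correlation). The iron-binding lipocalin Lcn2 rose by 2.53 ± 0.12, Apoa4 by 1.91 ± 0.08, Egr1 by 1.16 ± 0.11 and the chemokine Cxcl1 by 1.21 ± 0.19. Of the immediate early list Egr1 alone was called (adjusted p = 0.122 with an estimated correlation). The bile acid gene Slc27a5, the PPAR alpha target Acaa1b and the histidine-degrading Hal fell, while Cyp4a14, Oat and Mt1 rose. Of 21 xenobiotic genes Gstm3 rose and Gsta3 fell (adjusted p = 0.199 with an estimated correlation). Leaving out any 1 of the 4 arrays compared ended the limma calls of Cyp4a14, Oat and Psmb8 (adjusted p up to 0.284, 0.129 and 0.385). Gsta3 lost its call without Scap knockout replicate 1 or either wild type array (adjusted p up to 0.221), and Tap1 without Scap knockout replicate 1 or wild type replicate 2 (adjusted p up to 0.0652). Cxcl1 and Slc27a5 lost theirs without replicate 2 of either pool (adjusted p up to 0.0893 and 0.0565), and Hal fell short of 1.5-fold without Scap knockout replicate 1 (-0.52) or wild type replicate 2 (-0.55). Limma called 0 of 92 members in 12 lists, where 19 had an unadjusted p under 0.05. Among these, medians stood outside the middle of the random lists for stellate cell (0.23), unfolded protein (0.11) and endothelial genes (-0.11), with adjusted p = 0.0595, 0.124 and 0.331 with an estimated correlation. Lymphocyte marker Ighm fell (-0.69 ± 0.08), but its plain _at probe set stood at 0.08.

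Genes of other tissues stood among the largest differences of this comparison. All 7 exocrine pancreas markers fell, 7 adjusted over the list alone, with Prss2 at -4.21 ± 0.07 and Ctrb1 at -2.98 ± 0.08 (adjusted p = 0.00645 with an estimated correlation, or 0.0595 with the block as well). Rnase1 and 2210010C04Rik, also among the largest decreases, fell by 2.31 ± 0.13 and 2.46 ± 0.08. Of 22 skeletal muscle genes, a list made after the data were seen, 5 rose, including Acta1 and Myh1 by 2.69 ± 0.14 and 1.49 ± 0.20. Of 16 squamous epithelium genes, listed likewise, 6 rose, among them Krt4, Krt13, Sprr1a and Krtdap by 2.57 ± 0.12, 1.94 ± 0.13, 1.32 ± 0.09 and 1.29 ± 0.12. In total 61 genes were higher and 76 lower, 19 and 34 of them by 2-fold. Fewer were higher without replicate 2 of Scap knockout (39), without replicate 1 of wild type (40) or with 32 added (39). Without genes of these tissues, a choice made after the data were seen, 118 remained called.

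The combined analysis asked which genes were higher in both transgenic pools and lower without Scap. There were 30 such genes, where 0.976 would be expected of independent lists. Genes higher in both transgenic pools, 106 in all, overlapped those lower in Scap knockout beyond chance (Fisher's exact test, two-sided, p = 1.75e-38, over genes, which are not independent replicates). Of the 30, 13 belong to cholesterol synthesis and 7 to fatty acid and triglyceride synthesis, and 10 to neither. The cholesterol genes were Hmgcs1, Mvd, Idi1, Fdps, Fdft1, Sqle, Lss, Cyp51, Tm7sf2, Msmo1, Nsdhl, Hsd17b7 and Dhcr7. The fatty acid genes were Acly, Slc25a1, Fasn, Elovl6, Fads1, Me1 and Gpam. The 10 in neither were Srebf1, Tmem97, Cyb5b, Lpcat3, Acsl5, Aldoc, Tff3, Hes6, Bhlhe40 and H2-Q4. Tmem97, a sterol-binding membrane protein, stood at 1.90, 1.85 and -0.98 in TgSREBP-1a, TgSREBP-2 and Scap knockout. The lysophospholipid acyltransferase Lpcat3 stood at 1.41, 0.86 and -0.82, the aldolase Aldoc at 1.23, 1.66 and -0.78, and the trefoil factor Tff3 at 0.84, 1.11 and -0.73. By 2-fold in all 3 comparisons, 14 genes remained. When each array was left out in turn, 7 of the 30 lost a call at least once, namely Acsl5, Bhlhe40, Elovl6, H2-Q4, Hes6, Hsd17b7 and Slc25a1. Elovl6 in Scap knockout, for example, reached an adjusted p = 0.153 in limma without wild type replicate 2.

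**Figure D2:**
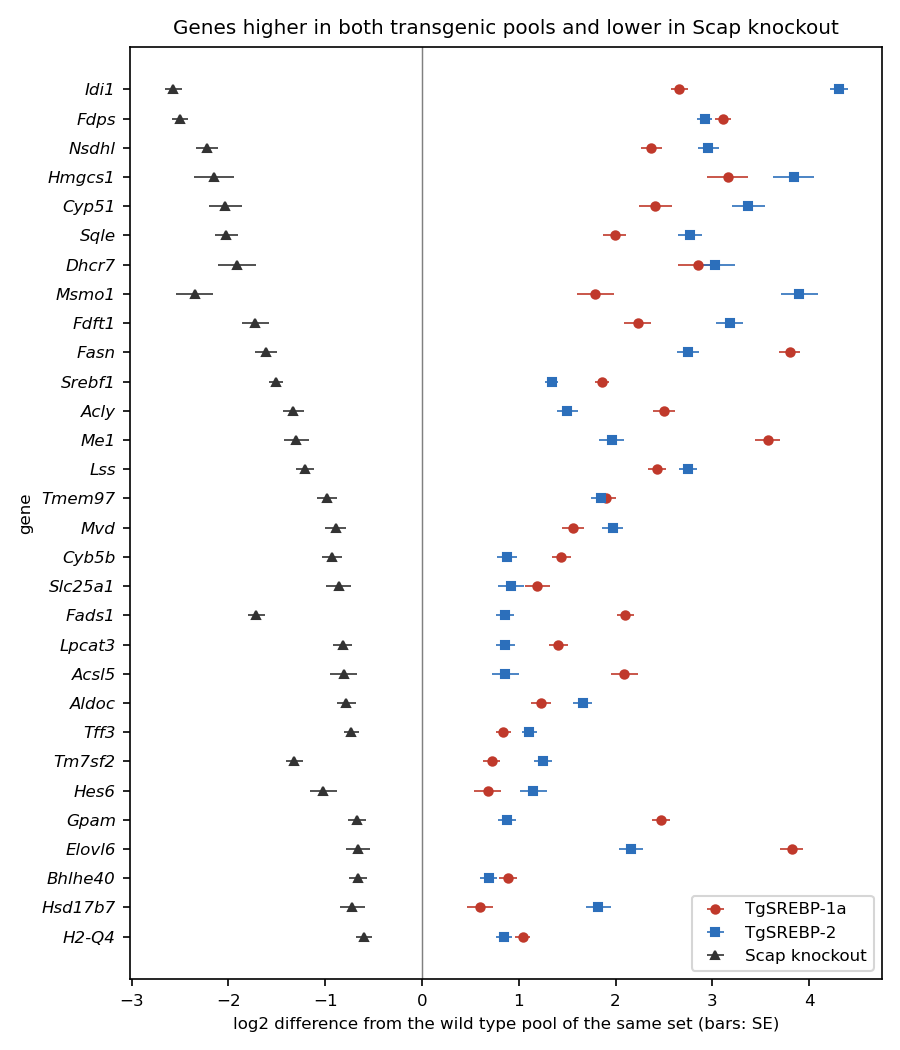
Log2 difference from the wild type pool of the same diet (x axis, bars are standard errors, n = 2 arrays per group) for the 30 genes (y axis) higher in TgSREBP-1a (red circles) and TgSREBP-2 (blue squares) and lower in Scap knockout (black triangles). Idi1 stands at the top with 2.66, 4.31 and -2.57, and H2-Q4 at the bottom with 1.04, 0.85 and -0.60.

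The opposite pattern, lower in both transgenic pools and higher in Scap knockout, held for 3 genes, Car14, Krt4 and Krt13. Krt4 and Krt13 are among the squamous epithelium genes above, and the wild type pools themselves differed in them. Their mean log2 signals were 9.37 and 6.12 in wild type on the high-protein diet against 7.92 and 4.97 on chow. Apoa4, Lcn2, Mgst3 and Ugdh were higher in all 3 comparisons. TgSREBP-1a and Scap knockout shared 23 lower genes where 1.97 would be expected of independent lists, and the 7 pancreas markers were among the genes lower in both. Across 8251 genes, which are not independent replicates, the log2 differences of TgSREBP-2 and Scap knockout correlated at r = -0.32 (Spearman -0.11), and those of TgSREBP-1a and Scap knockout at r = -0.02. The transgenic comparisons correlated at r = 0.52, and unchanged groups sharing the same controls gave 0.50 in simulation. Their covariance was 0.058 against a simulated 0.0064. The simulation held only the spread between hybridisations, so a deviation of the shared wild type pool itself could also raise the covariance. With the difference between the wild type pools, which shares that pool, covariances were -0.05 for TgSREBP-1a and -0.042 for TgSREBP-2. No conclusion on shared effects is drawn from the covariance. The transgenic comparisons shared 106 higher genes where 8.6 would be expected of independent lists. Simulated unchanged groups gave 0, but had at most 1 gene called in TgSREBP-1a and held only the spread between hybridisations. That 0 is therefore no yardstick for the overlap. Part of the excess over 8.6 may come from the shared control arrays, which are 2 of 1 pool and were not split.

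The wild type pools served as the yardstick of differences without a transgene or knockout. Diet, age, injections and possibly strain differ between them together. In the high-protein pool 106 genes were higher and 358 lower than in the chow pool, or 165 and 301 without replicate 2 of the high-protein pool, and with 32 added 237 were lower. The metallothioneins Mt1 and Mt2 were higher by 5.19 ± 0.08 and 4.51 ± 0.09, Saa2 by 2.99 ± 0.12, and the PPAR alpha targets Cyp4a14, Pdk4 and Cyp4a10 by 2.66 ± 0.19, 2.23 ± 0.18 and 2.03 ± 0.16. Cholesterol genes were lower, 12 of 16 or 13 adjusted over the list alone, with Hmgcs1 at -2.57 ± 0.21 and Idi1 at -2.51 ± 0.09 (adjusted p = 0.134 with an estimated correlation). Me1 stood at -2.76 ± 0.13 and Srebf1 at -1.42 ± 0.07. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -1.37 ± 0.16. Of 16 interferon-stimulated genes 11 were lower, 11 adjusted over the list alone, led by Ifit1 (-1.89 ± 0.12), with an adjusted p = 0.134 with an estimated correlation. The chow pool had received the polyinosinic-polycytidylic acid injections, so diet, age, injections and possibly strain cannot be told apart for this difference. From the Scap knockout pool the high-protein pool differed by a median of 0.22 (range -0.42 to 0.75) for cholesterol genes and 0.35 (range -1.46 to 2.31) for fatty acid genes. The transgenic increases in cholesterol genes were thus measured from a low control. Mean log2 signals in TgSREBP-1a and chow-fed wild type were 10.69 and 10.54 for Idi1 and 10.16 and 9.57 for Hmgcs1. For Sqle they were 9.77 and 9.50, and for Fasn 12.29 and 10.16, differences not tested. Markers of other tissues differed between the wild type pools too, with 6 of 7 pancreas genes higher (adjusted p = 0.134 with an estimated correlation), 4 of 11 macrophage markers lower (adjusted p = 0.22 with an estimated correlation) and 5 of 22 muscle genes higher in the high-protein pool.

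**Figure D3:**
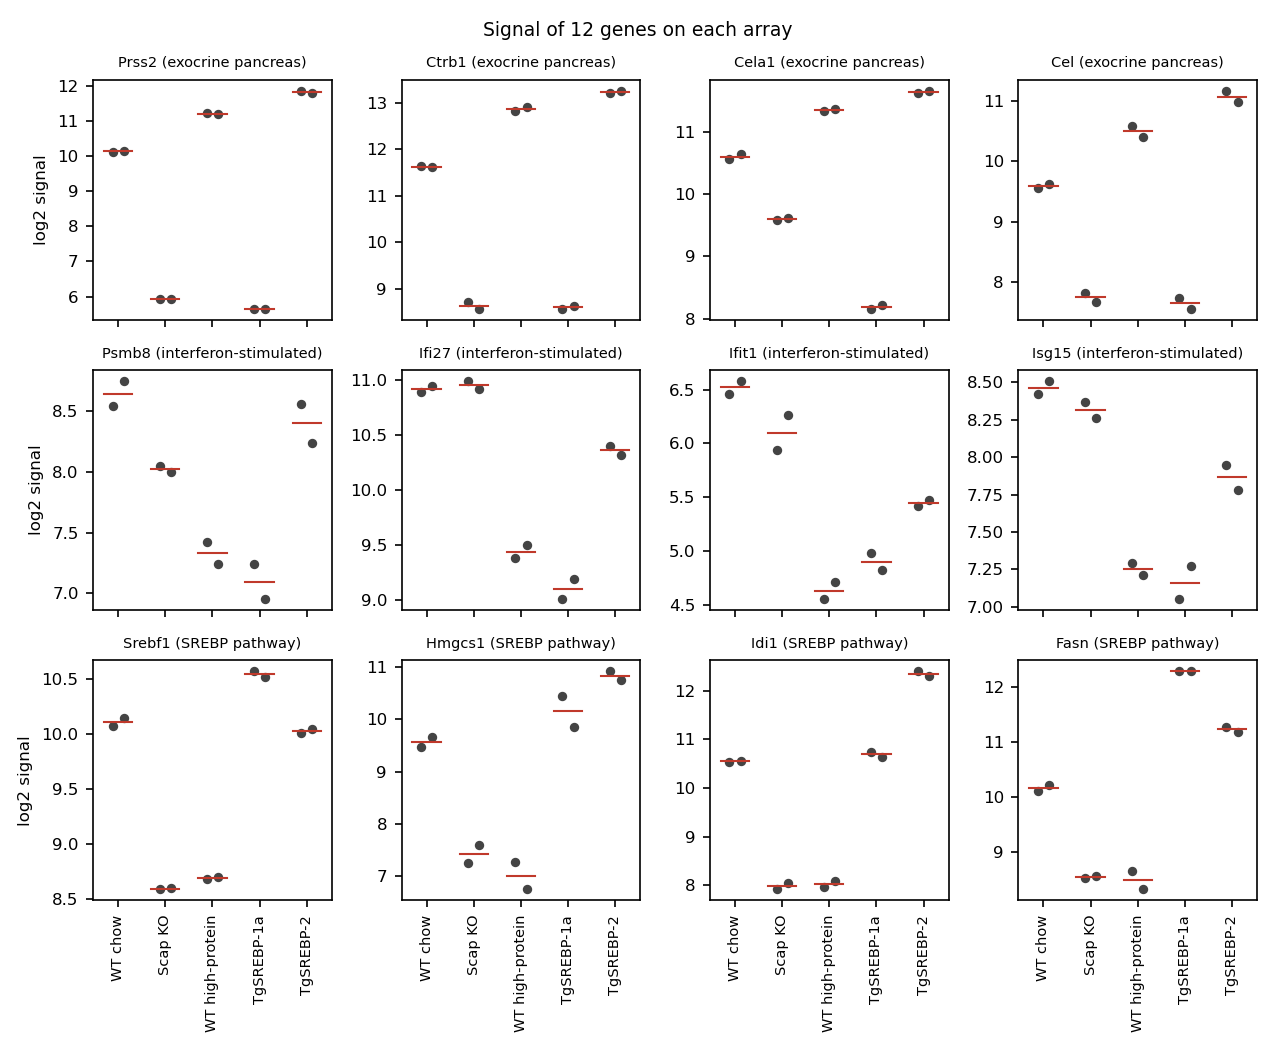
Log2 signal (y axis, own scale in each panel) of 12 genes on each array for the 5 pools (x axis); points are the 2 arrays of a pool and red lines their means. The pancreas genes (top row) are low in Scap knockout and TgSREBP-1a, with Prss2 means of 5.94 and 5.65 against 10.14 or more in the other pools, and Idi1 means are 7.98 in Scap knockout and 8.03 in wild type on the high-protein diet.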

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

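The tests of SREBP-driven acinar expression, of the wild type level, of macrophages, of muscle and of squamous epithelium were chosen after the results were seen, while the acinar genes outside the marker list were chosen before their values were seen. The test of squamous epithelium first counted against that explanation. Its criterion was then changed, with that outcome known, to ask also whether the probe sets were seen to respond. The same condition was set for muscle. In both it bears only on a count against the explanation, not on one for it. The test of SREBP-driven acinar expression replaced one whose outcome the pattern itself fixed.

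Against the same wild type pool, 14 genes were called in opposite directions in the transgenic pools, a choice that nearly fixes the limma call of their difference TgSREBP-1a minus TgSREBP-2. This difference was -6.19 for Prss2, -3.59 for Rnase1, -3.06 for Reg1, -2.58 for Sycn and -1.84 for Klk1, which the exocrine pancreas expresses strongly. It was -2.56 for Saa2, -2.39 for Noct, -1.67 for Atp11a and -1.46 for Igtp. It was 2.67 for Cyp2c39, 2.19 for Cyp4a10, 2.01 for Hamp, 1.90 for Acot1 and 1.66 for Retreg1.

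Among the 1589 probe sets without a single gene name, 76 were called in TgSREBP-1a, 32 in TgSREBP-2 and 24 in Scap knockout. The 18S rRNA control probe set differed between duplicates of 1 pool, replicate 2 minus replicate 1, by 2.44 in wild type on the high-protein diet, 1.86 in TgSREBP-1a and 2.03 in TgSREBP-2.

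Exocrine pancreas genes were low in TgSREBP-1a and Scap knockout and high in the other 3 pools, where Ctrb1 reached mean log2 signals of 11.62 to 13.23. All 7 markers were called lower both with added SREBP-1a and with lost Scap. Prss2 stood at -5.56 and -4.21, and Reg1 at -1.62 and -2.04. An effect of SREBP activity in 1 direction would move them oppositely in these pools. The pattern itself, without a separate test, therefore argues only against such an effect as the sole cause of both falls. An effect of this kind beside another cause stays open. In TgSREBP-2, outside the pattern, the 7 markers had a median of 0.58 with 2 called higher. That value alone decides nothing, since an effect of SREBP-1a alone also allows it. Pancreas tissue carried along with some livers is a candidate explanation. The 5 acinar genes outside the marker list had medians of -0.37 in TgSREBP-1a and -0.16 in Scap knockout, all below 0 but too small to decide, led by Ctrl at -1.27 and -0.43. Means of Cuzd1 (5.07 to 5.31) and Pla2g1b (9.18 to 9.35) barely differed between pools, so their probe sets may not respond. Rnase1 (-2.97 and -2.31), Sycn (-1.87 and -0.98) and Klk1 (-1.15 and -1.24) fell in both comparisons, but were picked by their values and so test nothing. A shared effect of both genotypes on acinar transcripts stays open and untested.

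Of 16 interferon-stimulated genes 7 were called higher in TgSREBP-2 by limma, with a median of 0.49 (adjusted p = 0.0695 with an estimated correlation). A low wild type pool alone would also raise TgSREBP-1a, whose median was 0.01. By mean log2 signal, every measured interferon-stimulated gene but B2m was lower in TgSREBP-2 than in the injected, chow-fed wild type pool, a difference not tested. Ifi27, for example, stood at 10.36 against 10.92, and B2m at 12.27 against 11.96. Of 11 macrophage markers 3 were called higher in TgSREBP-2 than in wild type by limma (median 0.24, adjusted p = 0.14 with an estimated correlation). No marker was higher in TgSREBP-2 than in TgSREBP-1a, where the differences were 0.08 to 0.77 with a median of 0.32 and 1 called (limma, adjusted p = 0.0883 with an estimated correlation) against -0.42 for interferon genes, which argues against macrophages as the whole cause. A response to SREBP-2 and an immune difference of single mice within a pool stay open, and neither was tested.

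Some skeletal muscle and squamous epithelium genes, 5 of 22 and 6 of 16, were called higher in Scap knockout than in its wild type. For muscle, the 18 list genes other than the 4 that drew attention had a median of 0.14, above all 10000 random lists. Ckm (0.02) and Mylpf (0.17), abundant in muscle, barely differed, and only 3 of the 18 differed by 1.5-fold between any 2 pools. With so few responding, the changed criterion could not have counted against muscle tissue, so no conclusion is drawn from the median. A small amount of muscle tissue stays a candidate. For squamous epithelium, the 10 other genes had a median of 0.03, at the 72.24 percentile, and none differed by 1.5-fold between any 2 pools, so their probe sets may not respond and, under the changed criterion, this decides nothing. Acta1 was also high in wild type on the high-protein diet (8.82) and, less so, in TgSREBP-2 (8.53), against 8.90 in Scap knockout. It was low in chow-fed wild type (6.21) and in TgSREBP-1a (5.71), and so lower in TgSREBP-1a than in its own wild type. Myh1, Myl1, Myl3 and Tnnt3, picked by their values, were high and low in the same pools. Myl1, for example, stood at 7.40 in Scap knockout, 7.14 in high-protein wild type and 7.21 in TgSREBP-2. In chow-fed wild type and TgSREBP-1a it stood at 6.37 and 6.45. An effect of Scap loss was not tested.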

How the results depend on the processing

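The blocks within experiments, the crossed numbers and the removal of other-tissue genes were chosen after seeing the data. Counts in this paragraph are for TgSREBP-1a, TgSREBP-2, Scap knockout, TgSREBP-1a against TgSREBP-2, the wild type pools and the 3-way overlap, in that order. They were 608, 212, 137, 428, 464 and 30, and stayed within 1.5 times of these under the settings run except the following, whose cause is their construction as stricter or looser thresholds. At 2-fold they were 240, 72, 53, 185, 110 and 14, at 3-fold 107, 29, 25, 75, 31 and 10, and with treat 236, 55, 41, 169, 84 and 14. With adjusted p alone the first 5 were 1366, 417, 234, 911 and 1869. With each array left out they ranged from 564 to 734, 143 to 255, 100 to 145, 411 to 479, 341 to 593 and 24 to 33, where the lone array is assumed to vary like the other groups. The correlation of TgSREBP-2 with Scap knockout moved from -0.32 to -0.36 with 32 added and without dim genes, and the cause was not tested. Ighm reversed on plain _at probe sets, which use another probe set of the gene, to -0.14 in TgSREBP-1a, 0.08 in Scap knockout and 0.55 between the wild type pools. The immediate early list reversed in TgSREBP-1a without dim genes, to -0.20, over fewer members. Of 631 named gene results, 46 lost the call when some array was left out. The 631 include results not called in the main fit, which had no call to lose. With an estimated correlation, 55 list results that stood outside the middle of the random lists did not pass in camera. The 80 that were the same include lists that stood out in neither. Of the 27 lists, 2, 1, 3, 1 and 0 passed in the 5 comparisons, in the order above. Values near the array's background limit the folds of dim genes, and with 32 added 28 named results were no longer called.

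With the replicate number as a block the counts were 614, 218, 139, 432, 471 and 31. With a block within each experiment they were 618, 229, 150, 442, 479 and 33; no call was lost, and 7 named gene results gained one. In set tests with an estimated correlation that block changed no call other than those given in the text. Without other-tissue genes the counts were 589, 208, 118, 412, 448 and 30. With the numbers crossed in the Scap set they were 617, 229, 148, 442, 478 and 33.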

Other observations

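Some histocompatibility genes, chosen after their values were seen and not tested as a group, were higher in the TgSREBP-1a pool, where 5 of 11 macrophage markers also rose. Of all 8251 genes 394 were higher there and 214 lower. Of 28 measured H2 genes 8 were higher, 20 were not called and none was lower. They were led by H2-Q1 at 3.25, with H2-Q4 at 1.04, H2-Q5 at 1.02 and H2-K2 at 0.96. H2-Q1 and H2-Q4 were read on _f_at probe sets, which may not separate similar genes, so the 8 may not be independent. In TgSREBP-2, where 3 of 11 macrophage markers rose, only H2-Q4 and H2-Q5 were higher, at 0.85 and 0.94. In Scap knockout H2-Q10 and H2-Q4 were lower, at -0.91 and -0.60. Between the transgenic pools, H2-Q1 alone of the 28 was called, at 3.31. The high-protein wild type pool, the control of both transgenic pools, itself differed from the chow pool, possibly also in strain. H2-Aa and H2-Q5 were lower in it, at -0.87 and -0.74, and H2-Ea was higher, at 0.64.

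Apoa4 and Lcn2 rose both with added SREBP and with lost Scap. Mean log2 signals of Apoa4 were 12.13 in TgSREBP-1a, 11.34 in TgSREBP-2 and 11.59 in Scap knockout against 9.53 and 9.68 in the wild type pools on the high-protein diet and chow. For Lcn2 they were 7.93, 8.41 and 8.10 against 7.12 and 5.57. Mt1 stood at 12.20 to 12.81 in the 3 pools on the high-protein diet and at 7.62 and 8.49 in the chow-fed wild type and Scap knockout pools.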
